A study of Homo sapiens with 21 samples.

How the data were processed

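Total RNA from skin biopsies was hybridised to the NanoString Human PanCancer Immune Profiling panel, per the labels. The table used holds a signal for each of 764 gene probes and 13 control probes (8 negative and 5 positive) in 21 samples, deposited by the authors. The software and the steps behind this signal are not given in the sources used here. In the deposited values each sample's gene signals lie on a ladder of equal steps, while the control probes are not scaled. The gene values are therefore read here as counts after background subtraction with a floor of 1, then scaled per sample, a reading that comes from the values. Dividing a sample's signal by its step gave its total counts after background. A further 21 columns of another table are named by run and lane, match no sample's labels and were not used here. Their names carry 4 run identifiers with 1, 2, 6 and 12 columns, so run effects were not tested.

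Groups came from the sample titles: healthy skin (n = 4), lesions before PUVA (n = 9) and lesions after PUVA (n = 8). The healthy skin came from plastic surgery and no lesion is labelled so, which makes the source of tissue and the group the same split. Patient numbers in the titles pair 8 of the patients, and the study's design text states that biopsies of the same patients were taken at both times; the pairing therefore comes from the person. After removing group means, the 2 libraries of a patient correlated at r = 0.018 to 0.721 across genes (median 0.453, against -0.086 for libraries of different patients; genes are not independent replicates), and 6 of 8 pre-PUVA libraries matched their own partner best. For 1 patient no post-PUVA library is among the samples. No libraries of a group were identical, the highest correlation being 0.958.

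Gene symbols are those of the file; 758 are current symbols in the RefSeq annotation of GRCh38.p14, 5 are older ones and 1 has no match there. No coordinates are printed. Probes of near-identical genes (alpha interferons, cancer-testis families, HLA class I) may share signal.

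Values were transformed as log2(value + 1) with no filter on low values. limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a mean-variance trend) compared lesions before PUVA with healthy skin and lesions after PUVA with healthy skin, each on its 2 groups alone, and lesions after with before PUVA on the 8 pairs with the patient as a block. Adjusted p-values are Benjamini-Hochberg values and a call means an adjusted p under 0.05; every adjusted p of a gene is limma's. The 30 gene lists, the rule for naming genes and the alternatives were fixed before the data were examined, except where stated. The list score is the mean log2 value over the measured members. The 29 lists with 3 or more measured members were tested with two-sided exact permutation tests (exact sign flips within patients) and adjusted over the 29; melanocyte markers had fewer. limma's camera was run with a preset inter-gene correlation of 0.01 and with an estimated one. The measure of a shift toward healthy skin takes, for each pair, the genes called between the other patients' pre-PUVA libraries and healthy skin (179 to 288 genes) and projects the pair's change on their differences; it was tested by exact sign flips.

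The genes named in the text were picked by a fixed rule. It takes for each comparison the 10 largest differences in each direction among called genes (within patients also moving that way in at least 6 pairs), or, with fewer than 10 called, the 10 with the smallest p. From each list it takes up to 4 members with the smallest adjusted p, and it also allows every interferon ligand and every called interferon-stimulated gene. XIST, sex-linked genes with a Y copy and genes whose level follows inherited gene content were not named. CD6, CD28, CTAG1B, FCGR1A, and the immediate early and stress genes as a group were chosen after their values were seen.

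The functions were tested on simulated data with 200 changed genes among 764, 100 each at a log2 change of 1 and 2. For lesions before PUVA against healthy skin 28.0% and 74.0% were recovered and 7 of 564 unchanged genes were called; after PUVA against healthy skin 40.0% and 66.0% with 5 unchanged genes called; and within patients 61.0% and 93.0% with 5 called. A simulated return of 0 gave a mean share of 0.00554 and one of 0.5 gave 0.412, so the share is slightly understated. The simulated genes varied independently of one another, with 1 data set per comparison. These rates therefore do not give the recovery where genes correlate or where fewer than 200 change.

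The alternatives were re-centring on reference genes (40 of 42 measured) or on each sample's median, quantile normalisation, a pseudocount of 10, leaving out the lowest 25% of genes, eBayes without the trend and with robust estimation, the patient as a random block, no replicate block, pre-PUVA samples with a partner only, z-scored lists, the shift over all genes, and leaving out each healthy replicate or patient in turn. Re-centring on reference genes changes little outside replicate number 14, since their mean level is nearly equal in the other 19 libraries. Floors at 27.9 and at 100 and the joint removal of replicate numbers 5 and 14 were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.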

Results

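RNA from skin was profiled in 21 libraries with a NanoString panel of 764 gene probes centred on immunity and cancer, in which colour-coded probes count RNA molecules without amplification. Healthy skin removed at plastic surgery gave 4 libraries. Lesions of mycosis fungoides gave 9 libraries before PUVA and 8 after PUVA, and 8 patients had libraries from both times. Mycosis fungoides is a lymphoma of T cells that home to the skin. PUVA combines a psoralen, which makes DNA sensitive to light, with ultraviolet A. After background subtraction the gene probes summed to 403381 to 701186 counts per library in healthy skin, 608750 to 1399530 before PUVA and 32484 to 1266910 after PUVA. The smallest total belonged to post-PUVA replicate 5, where 358 genes exceeded the highest negative control. There 1 count was worth 27.9 units after scaling, against 0.69 to 1.59 units in the other 20 libraries. The mean log2 level of the measured reference genes lay between 8.67 and 8.68 in 19 libraries and at 8.16 in both libraries with replicate number 14. Values below are on the log2(value + 1) scale, which understates the change of genes near the floor.

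Lesions before PUVA were first set against healthy skin, to ask which immune genes differ in mycosis fungoides before this treatment. CCL18, a chemokine of alternatively activated macrophages and dendritic cells, rose the most, by 6.45 ± 0.95 on the log2 scale or 87.1-fold (SE, n = 9 and 4, limma adjusted p = 0.000732). It lay above all 4 healthy libraries in 9 of 9 lesions. The T cell receptor chain CD3D rose 12.2-fold (log2 difference 3.61 ± 0.63, adjusted p = 0.0019). The complement subunit C1QB rose 10.3-fold (3.37 ± 0.56, adjusted p = 0.00168). The B cell antigen MS4A1 rose by 4.41 ± 1.08 on the log2(value + 1) scale (adjusted p = 0.00948), from a level that exceeded the highest negative control in 0 of 4 healthy libraries. The immediate early transcription factors FOS and EGR1, which respond within minutes to growth factors and stress, fell the most. FOS was 24.4-fold lower (-4.61 ± 0.59, adjusted p = 0.000435) and EGR1 11.5-fold lower (-3.52 ± 0.50, adjusted p = 0.000609). Both lay below all 4 healthy libraries in 9 of 9 lesions. In all, limma called 126 genes higher and 100 lower of 764, and 317 genes had an unadjusted p under 0.05.

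Pan T cell markers rose as a group. Their mean log2 level was 8.44 ± 1.23 (SD, n = 9) in lesions before PUVA and 5.88 ± 0.33 (SD, n = 4) in healthy skin, a difference of 2.55. Each of the 9 lesions lay above all 4 healthy libraries (two-sided exact permutation p = 0.0014, the smallest that 715 splits can give; adjusted over 29 lists, p = 0.0101). limma's camera called this list at its preset correlation and not with an estimated one (adjusted p = 0.714). Of 15 measured markers, 13 rose over all genes tested and 15 rose when adjusted over the list alone. Besides CD3D these included CD2 (3.21 ± 0.67), CD3E (3.09 ± 0.65) and the signalling adaptor SH2D1A (2.98 ± 0.66). CD6 and CD28 were the members that did not pass over all genes, and both were chosen after their values were seen. MHC class I presentation genes also rose as a group, by 1.10 from 10.27 ± 0.11 (SD, n = 4) to 11.37 ± 0.53 (SD, n = 9). Again 9 of 9 lesions lay above every healthy library (exact permutation p = 0.0014, adjusted p = 0.0101). The call of camera did not hold with an estimated correlation (adjusted p = 0.714), and the difference was 0.53 after median re-centring and 0.61 after quantile normalisation, both passing. Of its 12 measured members 7 rose over all genes and 8 when adjusted over the list alone. They were led by HLA-G (2.47 ± 0.35), the peptide transporter TAP1 (1.48 ± 0.35) and the immunoproteasome subunits PSMB9 (1.60 ± 0.43) and PSMB8 (1.28 ± 0.25). The HLA class I genes are close relatives, so a share of the HLA-G signal from its neighbours is not excluded here.

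Type I interferon ligands, the cytokines named in the title of the series, were lower in lesions before PUVA than in healthy skin. Their mean log2 level was 3.35 ± 1.19 (SD, n = 9) against 6.08 ± 0.69 (SD, n = 4), a difference of -2.73 on the log2(value + 1) scale. Each of the 9 lesions lay below every healthy library (exact permutation p = 0.0014, adjusted p = 0.0101). With an estimated correlation the call of camera did not hold (adjusted p = 0.714). The difference was -1.19 with every value below 27.9 raised to it and -0.27 with a floor at 100, each with an adjusted p of 0.0135. All 6 measured members fell, over all genes and when adjusted over the list alone. The differences were -3.02 ± 0.70 (SE) for IFNA7, -3.02 ± 0.76 for IFNA17, -2.88 ± 0.65 for IFNA8, -2.59 ± 0.71 for IFNB1, -2.52 ± 0.70 for IFNA2 and -2.37 ± 0.58 for IFNA1. In scaled units the IFNB1 value was 42.4 ± 12.9 (SD, n = 4) in healthy skin and 9.53 ± 9.50 (SD, n = 9) before PUVA. In 4 of 9 lesions IFNB1 exceeded the highest negative control of the library. The alpha interferon genes are near-identical copies, so their probes may share signal. The interferon-stimulated genes, which are switched on by these cytokines and by interferon-gamma, lay in the opposite direction. Their mean was 9.54 ± 0.71 (SD, n = 9) before PUVA and 8.36 ± 0.12 (SD, n = 4) in healthy skin, a difference of 1.18, and 8 of 9 lesions lay above every healthy library. This did not pass after adjustment (exact permutation p = 0.0154, adjusted p = 0.0811), and the difference was 0.61 after median re-centring and 0.70 after quantile normalisation, of which the latter passed (adjusted p = 0.0377). Of 17 measured interferon-stimulated genes 7 rose over all genes and 9 when adjusted over the list alone. Among them were IFI27 (2.41 ± 0.48), IFITM1 (1.88 ± 0.38) and OAS3 (1.47 ± 0.43).

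Cancer-testis antigens, genes of the germ line that some tumours express, fell beside the interferon ligands. Their mean log2 level was 3.29 ± 0.49 (SD, n = 9) before PUVA and 5.31 ± 0.29 (SD, n = 4) in healthy skin, a difference of -2.02. Each of the 9 lesions lay below every healthy library (exact permutation p = 0.0014, adjusted p = 0.0101). Here too the call of camera did not hold with an estimated correlation (adjusted p = 0.367), and with a floor at 100 the difference was -0.15, still passing. Of 25 measured members 21 fell, with the same number when adjusted over the list alone. They were led by CT45A1 (-3.21 ± 0.65), MAGEA3 (-3.21 ± 0.43), SSX4 (-3.20 ± 0.54) and SSX1 (-3.11 ± 0.55). CTAG1B was the 1 member that rose, and was chosen after its values were seen. Several of these genes have near-identical copies. MAGEA3 had a mean value of 61.8 ± 22.6 (SD, n = 4) in healthy skin and 6.14 ± 3.21 (SD, n = 9) before PUVA. The lambda interferon IFNL2 (-3.16 ± 0.41) and the cytokine IL17F (-3.11 ± 0.57) were also among the 10 genes that fell most. Among the 25% of genes with the lowest mean level, 191 in number, the median log2 difference was -1.11 and limma called 8 genes higher and 71 lower. The next 3 groups of 191 genes by level had medians of 0.32, 0.51 and 0.31.

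**Figure D1:**
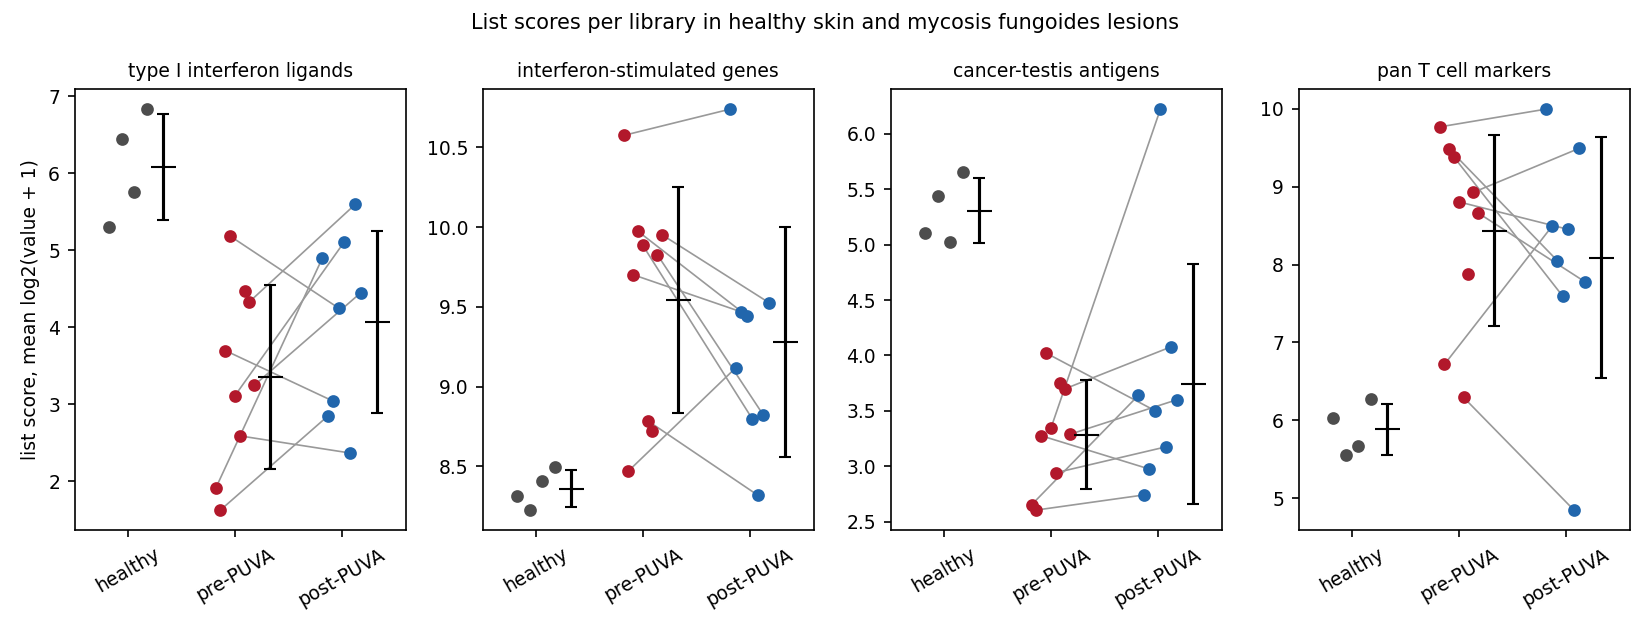
List scores, the mean log2(value + 1) over a list's measured members, for each library of healthy skin (n = 4) and of lesions before (n = 9) and after PUVA (n = 8); grey lines join libraries of the same patient, and black bars give the mean ± SD. Ligand and cancer-testis antigen scores of all 9 pre-PUVA libraries lie below the healthy ones, and the T cell scores of all 9 lie above them.

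Other cell type lists did not pass the adjusted test before PUVA on the values as deposited, although single members did. The number of lists that passed depended on the scaling, with 4 as deposited, 13 after median re-centring and 14 after quantile normalisation. Macrophage, dendritic and plasmacytoid dendritic cell markers passed under both, at 0.89, 0.69 and 0.97 after median re-centring and 1.06, 1.04 and 1.51 after quantile normalisation. With a floor at 100 the plasmacytoid dendritic cell markers differed by 0.51. All 3 also passed without healthy replicate 2 and without replicate number 2, where they differed by 1.65, 1.49 and 1.77 without the latter, and macrophage markers passed without number 6. Macrophage and monocyte markers differed by 1.46 (exact permutation p = 0.0196, adjusted p = 0.0811), and 8 of 16 members rose, including the mannose receptor MRC1 (3.08 ± 0.54) and the scavenger receptor CD163 (2.17 ± 0.49). FCGR1A was the 1 marker of that list that fell, and was chosen after its values were seen. Dendritic and Langerhans cell markers differed by 1.26 (adjusted p = 0.0862), with 7 of 16 higher, among them CCL13 (2.95 ± 0.68) and CD209 (2.36 ± 0.62). Plasmacytoid dendritic cell markers differed by 1.54 (adjusted p = 0.0811), with 2 of 6 higher. Of these CLEC4C rose by 3.49 ± 0.88 and the protease GZMB, which is also on the cytotoxic and NK list, by 2.95 ± 0.78. Cytotoxic and NK markers differed by 1.27 (adjusted p = 0.122), with 10 of 24 higher, and checkpoint receptors by 1.25 (adjusted p = 0.125), with 4 of 13 higher and LAG3 leading at 2.90 ± 0.65. These 2 lists differed by 0.70 and 0.68 after median re-centring, by 0.67 and 0.75 with a floor at 100, and by 1.45 and 1.19 after quantile normalisation, where both passed. Inflammatory cytokines and chemokines differed by -0.84 (adjusted p = 0.249). The difference was -0.16 with a floor at 100 and -1.04 to -0.53 with 1 library or patient left out. Of 20 members 1 rose and 4 fell, including the prostaglandin synthase PTGS2 (-2.89 ± 0.69), IL1A (-2.07 ± 0.60) and CXCL2 (-2.06 ± 0.70).

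The other lists did not pass before PUVA on the values as deposited either. Endothelial markers, DNA damage genes and complement genes passed under both median re-centring and quantile normalisation, at -0.75, -0.90 and -1.03 and at -0.64, -0.57 and -0.52. Interferon-gamma-inducible genes differed by 1.91 (adjusted p = 0.122) and MHC class II presentation by 1.26 (adjusted p = 0.125). B and plasma cell markers differed by 0.64 (adjusted p = 0.475), although MS4A1 and CD79A (2.59 ± 0.79) rose. Their difference was 0.076 after median re-centring, 0.26 with a floor at 100 and 1.10 after quantile normalisation, where it passed. Neutrophil markers (-0.75) and T helper 17 genes (-0.77) lay lower with an adjusted p of 0.168 each, and complement genes differed by -0.46 (adjusted p = 0.298). Regulatory T cell genes (0.76), T helper 2 genes (-0.15), mast cell markers (-0.17) and endothelial markers (-0.18) had an adjusted p of 0.305 or more. So did epidermal structural and adhesion markers (-0.41), DNA damage and apoptosis genes (-0.33) and proliferation genes (-0.27, with 4 of 10 listed genes measured). Reference genes differed by -0.06 (adjusted p = 0.94). Their mean level was nearly equal in 19 libraries, as scaling on them would give, so their test decides nothing. Genes of nucleic acid sensing (0.28, 21 of 28 listed genes measured) and fibroblast and matrix genes (0.42, 5 of 11) had an adjusted p of 0.271 or more. So did mycosis fungoides-associated T cell genes (0.39, 4 of 12) and epidermal alarmins (0.37, 7 of 16), lists of which most genes were not tested. Each of these 4 took a negative sign after median re-centring, as did nucleic acid sensing and the fibroblast genes after quantile normalisation. With a floor at 100, T helper 2 genes (0.31), T helper 17 genes (0.077), neutrophil markers (0.044) and complement genes (0.10) took a positive sign and did not pass. Median re-centring moved the median log2 difference of all genes by -0.57 and quantile normalisation by -0.42, and the share of called genes that were higher went from 55.8% to 30.3% and 47.2%.

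Leaving out healthy replicate 1, 3 or 4 took the genes called higher from 126 to 64, 70 and 75. Genes called lower numbered 24 without the lowest 25% of genes, 26 with a floor at 100, 66 with a floor at 1 count of the shallowest library and 209 after median re-centring, against 100. The adjusted p of ligands and of cancer-testis antigens was 0.0586 without healthy replicate 1 or 3 or without the patient with replicate number 1, 3, 5 or 14. That of pan T cell markers and of MHC class I was 0.0586 to 0.0879 without any 1 of these or without replicate number 4 or 8. With 1 library or patient left out the differences ranged from 2.35 to 2.82 for pan T cell markers and from 1.01 to 1.25 for MHC class I. Those of ligands and of cancer-testis antigens ranged from -2.96 to -2.40 and from -2.11 to -1.89. Fewer splits are possible with a sample left out, so the smallest exact p is larger. The lost calls can in part come from this limit of the test. The adjusted p of interferon-stimulated genes was 0.0251 without healthy replicate 2 and 0.00976, 0.0488 and 0.0469 without replicate numbers 2, 6 and 7. With limma's camera at a preset inter-gene correlation of 0.01, 11 of 29 lists passed before PUVA, 9 after PUVA and 7 within patients. None of these calls held with an estimated correlation, where the smallest adjusted p was 0.367, 0.806 and 0.695.

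**Figure D2:**
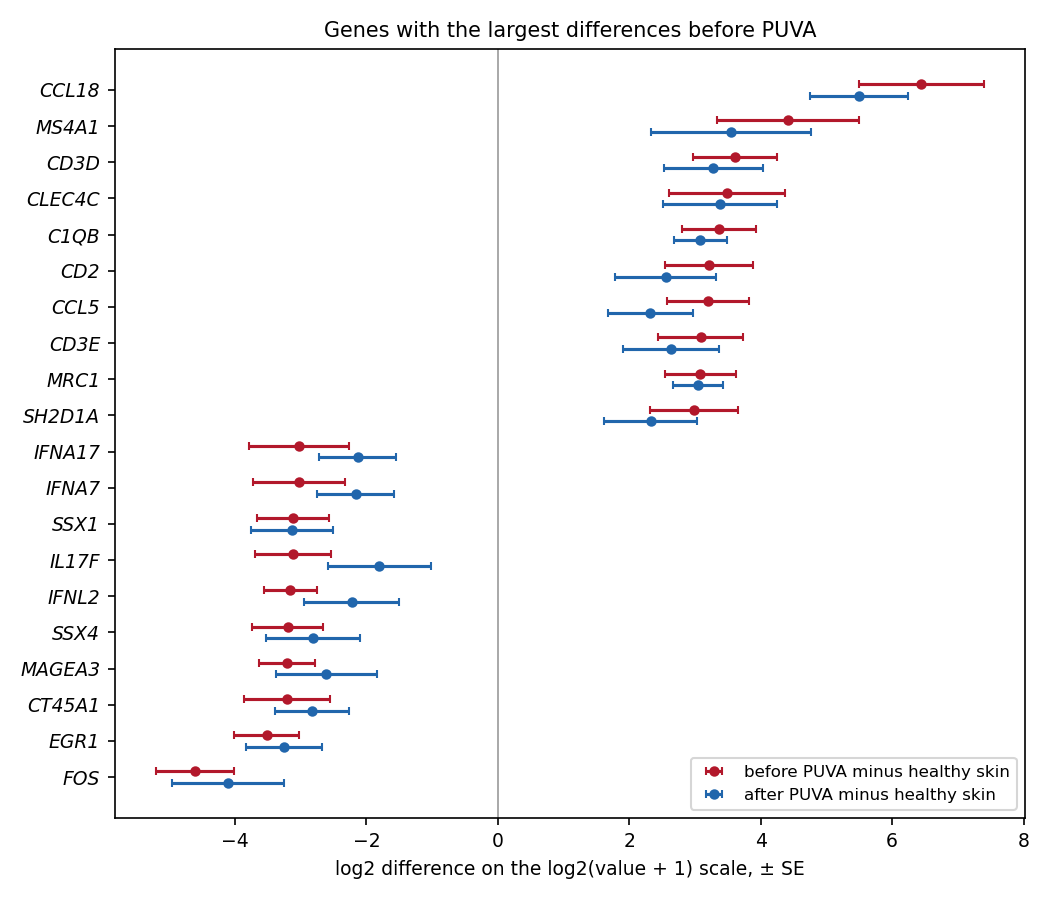
Log2 differences from healthy skin (n = 4) with their SE for the 10 genes that rose most and the 10 that fell most before PUVA (n = 9), with the values of the same genes after PUVA (n = 8). CCL18 lies at 6.45 before and 5.49 after PUVA, and FOS at -4.61 and -4.11.

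Lesions after PUVA were then set against the same 4 healthy libraries, to ask which differences were present once treatment had been given. CCL18 was again the gene with the largest rise, 45.0-fold or 5.49 ± 0.75 on the log2 scale (SE, n = 8 and 4, adjusted p = 0.000956), above all healthy libraries in 8 of 8 lesions. The macrophage genes C1QB (3.08 ± 0.40) and MRC1 (3.04 ± 0.38) rose with an adjusted p of 0.000876 each. The chemokine CXCL9 (3.53 ± 1.05), the plasmacytoid dendritic cell receptor CLEC4C (3.38 ± 0.86), the B cell receptor chain CD79A (3.31 ± 0.88) and the checkpoint receptor LAG3 (3.16 ± 0.89) rose with an adjusted p between 0.0234 and 0.0383. IL6 fell the most (-4.21 ± 1.36, adjusted p = 0.0465), followed by FOS (-4.11 ± 0.85, adjusted p = 0.00924) and EGR1 (-3.25 ± 0.58, adjusted p = 0.00736). IL6 lay below all healthy libraries in 4 of 8 lesions, and FOS and EGR1 each did in 8 of 8. limma called 98 genes higher and 39 lower of 764, and 259 genes had an unadjusted p under 0.05. The counts were 60 higher and 132 lower after median re-centring, which moved the median difference of all genes by -0.51, and 100 each way after quantile normalisation, which moved it by -0.34.

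After PUVA the type I interferon ligands had a mean log2 level of 4.07 ± 1.18 (SD, n = 8), -2.01 from healthy skin, and 7 of 8 lesions lay below every healthy library (exact permutation p = 0.0141, adjusted p = 0.0952). The difference was -2.53 after median re-centring, -2.03 after quantile normalisation and -0.27 with a floor at 100, each passing. IFNA7 (-2.16 ± 0.58), IFNA17 (-2.13 ± 0.58) and IFNB1 (-1.87 ± 0.61) fell over all genes, and 6 of 6 members fell when adjusted over the list alone. Interferon-stimulated genes had a mean of 9.28 ± 0.72 (SD, n = 8), a difference of 0.92 (adjusted p = 0.0952) that was 0.41 after median re-centring and 0.49 after quantile normalisation. Of its 17 members 7 were higher over all genes and 8 when adjusted over the list alone. IFI27 rose by 2.36 ± 0.51 and IFIT2 by 1.20 ± 0.38. Macrophage and monocyte markers came closest to passing, with a difference of 1.33 and 8 of 8 lesions above every healthy library (exact permutation p = 0.00202, adjusted p = 0.0586), and 9 of 16 members rose. This exact p is the smallest that 495 splits can give. A single list at it has an adjusted p of 0.0586 over 29 lists, so no list could pass alone here. Macrophage and monocyte markers passed without replicate number 5 or 6, with a difference of 1.26 and 1.43. Pan T cell markers differed by 2.20 (adjusted p = 0.0952), with 7 of 15 higher over all genes and 11 when adjusted over the list alone, among them CD4 (2.03 ± 0.41). Cancer-testis antigens differed by -1.56 (adjusted p = 0.0952), or by -0.10 with a floor at 100, with 6 of 25 lower and 7 when adjusted over the list alone. By the exact test 0 of 29 lists passed after adjustment on the values as deposited and 8 had an unadjusted p under 0.05. Several lists passed after median re-centring and after quantile normalisation, with the numbers given below under the processing.

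Without healthy replicate 1, 2, 3 or 4 the genes called higher numbered 29, 16, 21 and 12 and those called lower 10, 7, 10 and 2, against 98 and 39. Without replicate number 3, 4 or 6 the higher ones numbered 53, 55 and 160. Without the shallow replicate number 5 limma called 113 genes lower in place of 39, without numbers 3 and 4 it called 20 and 22, and the lists that passed numbered 2 without number 5 and 6 without number 6.

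Within patients, libraries after PUVA were compared with libraries before PUVA from the same person, to ask what the treatment changed and whether type I interferon expression rose with it. limma called 0 of 764 genes with the patient as a block, and 41 genes had an unadjusted p under 0.05, where chance gives 38.2. The median 95% confidence interval reached 0.68 to each side of a gene's log2 difference. The neurofilament gene NEFL had the smallest p, with a log2 difference of 1.83 ± 0.32 (SE, n = 8 pairs, adjusted p = 0.141), higher in 8 of 8 pairs. The decoy death receptor TNFRSF10C lay 1.36 ± 0.30 higher in 8 of 8 pairs and the antimicrobial protein LTF -2.35 ± 0.50 from its level before treatment, lower in 7 of 8 pairs (adjusted p = 0.239 for both). The cytotoxic T cell chain CD8B differed by -1.08 ± 0.26 and was lower in 8 of 8 pairs (adjusted p = 0.39), and the tissue-homing receptor CXCR6 by -1.39 ± 0.43 (adjusted p = 0.64). The fit with no replicate block also called 0 genes in either direction, as did the fits without a mean-variance trend and with robust estimation. With the patient as a random block over all samples, 1 gene, NEFL, was called higher.

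Type I interferon ligands differed by 0.86 ± 1.36 (SD of the paired differences, n = 8) after PUVA and were higher in 5 of 8 pairs, which did not pass (two-sided exact sign-flip permutation p = 0.109, adjusted p = 0.623). The mean difference was 0.53 after quantile normalisation, 0.49 with a pseudocount of 10, 0.15 with values below 27.9 raised to it and 0.0010 with a floor at 100. Without replicate number 1 it was 0.55. The largest member difference was that of IFNA8 (1.15 ± 0.39, higher in 8 of 8 pairs, adjusted p = 0.711), and IFNB1 differed by 0.87 ± 0.54. Cancer-testis antigens differed by 0.51 ± 1.06 (SD, n = 8) and were higher in 6 of 8 pairs (exact p = 0.195, adjusted p = 0.629). This difference was 0.18 without the shallow replicate number 5, 0.27 after quantile normalisation and 0.056 with a floor at 100. Interferon-stimulated genes differed by -0.37 ± 0.57 (SD, n = 8) and were higher in 2 of 8 pairs (exact p = 0.117, adjusted p = 0.623), with IFIT1 at -0.53 ± 0.21 and MX1 at -0.70 ± 0.34. MHC class I presentation differed by -0.32 ± 0.42 (exact p = 0.0781, adjusted p = 0.623), cytotoxic and NK markers by -0.52 ± 1.17 (adjusted p = 0.725) and pan T cell markers by -0.42 ± 1.22 (adjusted p = 0.788). With a floor at 100 the last 2 differed by -0.26 and -0.23. Without replicate number 4 they differed by -0.27 and -0.22, and pan T cell markers by -0.73 without number 2 and by -0.27 without number 3 or 6. By the exact test 0 of 29 lists passed, and 0 had an unadjusted p under 0.05. The 256 sign patterns allow an exact p down to 0.00781, so a single list could not pass alone after adjustment over 29.

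A last measure asked how far each lesion after PUVA had moved toward healthy skin, where 0 is no movement and 1 a full return. It runs along the genes that separated the other patients' lesions before PUVA from healthy skin. The mean over 8 pairs was 0.164 ± 0.239 (SD), positive in 7 of 8 pairs, and did not pass (two-sided exact sign-flip permutation p = 0.0859, adjusted over the 3 versions of the measure, p = 0.176). The genes higher before PUVA gave 0.137 ± 0.338 and the genes lower before PUVA 0.215 ± 0.355 (exact p = 0.273 and 0.117; adjusted over the 3 versions of the measure, p = 0.273 and 0.176). With replicate number 5 left out of the mean the lower genes gave 0.112, and the higher genes gave 0.080 without number 4 and 0.232 without number 2. Without healthy replicate 2 the mean was 0.216 and without the patient with replicate number 2 it was 0.222, each with an exact p of 0.0156. Without replicate number 5, whose post-PUVA library is the shallow one, it was 0.102 (exact p = 0.172), and without replicate numbers 5 and 14 it was 0.080 (exact p = 0.344). Quantile normalisation and a floor at 100 each gave 0.108.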

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

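Single values far from their group were sought with a fixed rule, on the genes and lists of the text, the genes CD6, CD28, CTAG1B and FCGR1A being chosen only after the result was seen. It compares the gap between the most extreme library and its neighbour with the range of the group (Dixon's ratio, groups of 4 to 10). Of 252 groups tested over 29 lists, 54 genes and the library totals, 24 had such a library, where chance gives about 1 in 20 groups, or 12.6. No explanation was tested for the values of this part. All levels are mean or single-gene log2(value + 1).

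Post-PUVA replicate 6 lay far below the other post-PUVA libraries in pan T cell markers (4.85), dendritic and Langerhans cell markers (6.87), CD3D (6.20), CD3E (5.29), SH2D1A (3.70) and CXCR6 (2.75). Its nearest neighbours had 7.59 in T cell markers and 9.63 in CD3D. These measures share genes and cells, so they are not independent.

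Post-PUVA replicate 5, the library with 32484 counts, lay far above the others in cancer-testis antigens (6.22), MAGEA3 (6.82), CTAG1B (7.62), T helper 17 genes (7.56) and neutrophil markers (5.67). 1 count is worth 27.9 units in this library.

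Both libraries with replicate number 14 lay far below their groups in reference genes, at 8.16 before PUVA and 8.16 after PUVA, where the nearest other library had 8.67.

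Among the other post-PUVA libraries MX1 was high in replicate 1 (12.90). Before PUVA the mycosis fungoides-associated T cell genes were high in replicate 1 (8.08), epidermal structural and adhesion markers low in replicate 4 (8.11) and IFIT1 low in replicate 7 (5.83). Among the 4 healthy libraries, CD2 was low in replicate 2 (3.08), CD28 (4.72) and CD79A (3.33) were low and MRC1 (8.15) was high in replicate 3, and regulatory T cell genes (6.83), CD6 (6.51) and EGR1 (12.74) were high in replicate 4.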

How the results depend on the processing

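The floors at 27.9 and at 100 and the joint removal of replicate numbers 5 and 14 were chosen only after the data were seen. The other table could not serve as an alternative, since its columns match no sample. Of 8405 values of single genes over 26 settings, 7624 kept their direction and their side of the threshold, 522 no longer passed, 155 newly passed, 103 that passed in neither changed sign and 1 reversed. Of 1789 list values over 24 settings these numbers were 1598, 32, 65, 94 and 0. Only a gene or list that passed with the main settings can stop passing. For lists these were 2 higher and 2 lower before PUVA, and 0 after PUVA and within patients. The 32 are therefore to be read against those lists alone, and most values that stayed the same never passed. The causes were not tested except where named.

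Median re-centring gave 209 genes lower and 13 lists before PUVA, and 60 genes higher, 132 lower and 10 lists after PUVA, with ligands at -2.53 after PUVA now passing. Quantile normalisation gave 14 lists before and 10 after PUVA, 100 genes lower after PUVA, interferon-stimulated genes at 0.70 before PUVA and ligands at -2.03 after PUVA, both passing. These settings moved the median difference by -0.57 and -0.42 before and by -0.51 and -0.34 after PUVA. Without the lowest 25% of genes 24 genes were lower before PUVA, 25 after PUVA, and 2 lists passed after PUVA; fewer genes are tested there, and the ligand list has no value. A floor at 1 count of the shallowest library gave 66 genes lower before PUVA, with ligands at -1.19 before PUVA, -1.05 after and 0.15 within patients. A floor at 100 gave 74 higher and 26 lower before PUVA with ligands at -0.27, ligands at 0.0010 within patients, and 62 higher, 21 lower, 2 lists and passing ligands at -0.27 after PUVA; MAGEA3 after PUVA against healthy skin reversed to 0.020, since the floor sets all but 1 of its values equal. With only paired pre-PUVA libraries the interferon-stimulated genes passed at 1.29. Without replicate numbers 5 and 14 no list passed before PUVA (0, ligands -2.68, with fewer samples) and 114 genes were lower after PUVA. With the patient as a random block 1 gene was higher within patients; with no replicate block 0 were, ligands differed by 0.72 and interferon-stimulated genes by -0.26.

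Leaving out 1 healthy library or 1 patient gave 64 to 183 genes higher and 71 to 107 lower before PUVA, with 0 to 9 lists, and 12 to 160 higher and 2 to 113 lower after PUVA, with 0 to 6 lists. Lists before PUVA numbered 0 without healthy replicate 1 or 3 or replicate number 1, 3, 5 or 14, 2 without number 4 or 8, 8 without healthy replicate 2 and 9 without number 2. The smallest possible exact p is larger in each, since fewer splits are possible. Genes higher before PUVA numbered 64, 70 and 75 without healthy replicates 1, 3 and 4. After PUVA the higher genes numbered 29, 16, 21 and 12 and the lower 10, 7, 10 and 2 without healthy replicates 1 to 4; without numbers 3 and 4 they were 53 and 20, and 55 and 22; without number 6 160 were higher with 6 lists, and without number 5 113 were lower with 2 lists. Within patients 0 genes and 0 lists passed in each. Ligands ranged from -2.96 to -2.40 before PUVA, -2.40 to -1.72 after and 0.55 to 1.12 within patients, and interferon-stimulated genes from 1.04 to 1.32, 0.69 to 1.06 and -0.51 to -0.26. The shift toward healthy skin ranged from 0.102 without number 5 to 0.222 without number 2, passing by its unadjusted exact p without number 2 and without healthy replicate 2 (0.216). Over the other settings it lay between 0.080, without numbers 5 and 14, and 0.169, after median re-centring, and passed in none.

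Signal over background limits the shallow post-PUVA replicate 5, where 358 genes exceeded the highest negative control, against 618 or more in the other libraries.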

Other observations

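The tests of the shallow library, of the ligands against level-matched probes in each library, of FOS and EGR1, and of other splits of the samples were chosen only after the result was seen.

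Interferon ligands lay lower in lesions before PUVA than in healthy skin, as did most other probes of low level. The median difference of the 6 ligands, -2.73, lay at percentile 0.03 of 10000 random lists matched on level, whose median was -0.98. The random lists here and below hold unrelated genes, while the ligands had an estimated inter-gene correlation of 0.76. Such a percentile is therefore not a p-value and decides nothing alone. Measured in each library against the mean of the 40 probes nearest in level to each ligand, the ligands still differed by -1.95 (two-sided exact permutation p = 0.0014, the smallest possible). This argues against a rise of signal spread evenly over the low probes of healthy skin as the whole cause. The unscaled ligand counts were 5.48 times higher in healthy skin (two-sided exact permutation p = 0.0112), which argues against the scaling of the shallower healthy libraries. Less type I interferon transcript in lesions before PUVA would give the same values. An uneven rise shared by ligands and cancer-testis antigens stays open, since the latter, which lie outside interferon biology, lay at percentile 0 of their matched lists (-2.25 against -1.12). Run effects and the surgical source of the healthy skin stay open too. A hypothesis to test is that the low probes of healthy skin carry true transcript. Quantitative PCR with gene-specific primers on the same RNA would bear on it without deciding it alone. Near-identical copies may share signal there too, and the surgical source of the healthy skin would stay open.

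Interferon ligands were higher on average after PUVA without passing the test. The shallow post-PUVA library stays open as a source of that mean. Without replicate number 5 it was 0.70 ± 0.52 (SE, n = 7), which lies above the bound of 0.43 set for it by less than its SE. With every value below the worth of 1 count in that library raised to it the mean was 0.15, and with a floor at 100 it was 0.0010, so the difference lies at levels that this library cannot resolve. A rise of signal under low probes of every kind stays open, with values on both sides. Over the 8 pairs the ligand change followed the change of cancer-testis antigens with a Pearson r of 0.679 (two-sided exact permutation p = 0.0472) and a Spearman rho of 0.905 (exact p = 0.00456). Adjusted over the 2 relations computed, these p-values were 0.0943 and 0.00913, so the Pearson value did not pass. Without the 2 pairs farthest from the median r was 0.901 (exact p = 0.0194) and rho 0.829 (exact p = 0.0583), so the rank relation no longer passed. Without replicate number 5 r was 0.926 and rho 0.893 (exact p = 0.00278 and 0.0123). Against it, the median ligand change of 0.93 lay at percentile 99.7 of level-matched random lists, whose median was 0.36. That of cancer-testis antigens, 0.50, lay at percentile 97.1 of their own matched lists, whose median was 0.35, so a high percentile was not particular to the ligands. The random lists hold unrelated genes, so these percentiles are not p-values and decide nothing alone. Measured in each library against the probes nearest in level the change was 0.54 ± 0.89 (SD, n = 8), higher in 5 of 8 pairs, which did not pass (two-sided exact sign-flip permutation p = 0.125). No relation of the ligand change to that of interferon-stimulated genes was detected (r = 0.109, rho = 0.00, exact p = 0.792 and 1). A restored production of interferon, the biological explanation that the design names, stays open.

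FOS and EGR1 were lower in lesions than in healthy skin, and the values here are those before PUVA unless stated. The tables argue against signal near the floor, since their mean difference was -4.04 with every value below 100 raised to 100, where the larger adjusted p was 0.000875. The handling of surgical skin cannot be told apart from the healthy group, because every healthy library is surgical. The 8 other immediate early and stress genes measured had a median difference of -1.02 at percentile 0.05 of matched lists, which handling could give, as could the disease itself. Of these 8 limma called only CXCL2 and PTGS2 lower before PUVA (adjusted p = 0.0405 and 0.00881), and DUSP4 lay 0.34 higher. After PUVA limma called CXCL2, PTGS2 and also IL6 lower (adjusted p = 0.0245, 0.0383 and 0.0465), and DUSP4 lay 0.22 higher. The median of the 8 was then -1.22, at percentile 0 of matched lists. The matched lists hold unrelated genes, so the percentile is not a p-value. These 8 were picked after the values of FOS and EGR1 were seen. Healthy skin sampled outside surgery would separate these.

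Other splits of the samples were counted for the gene calls of each comparison. For lesions before PUVA against healthy skin 1 of 100 splits, the real one, gave as many genes (226 against 10 in the highest other). For lesions after PUVA 1 of 100 did (137 against 0), so counts this high were rare among the splits. The 100 splits are a sample of those possible, so a share under 1 in 100 cannot be seen. Mixed splits also carry the group difference as spread within groups, so the margin over them does not measure strength. Within patients limma called 0 genes in the real split, with 41 at an unadjusted p under 0.05. Any split reaches a count of 0, so the 100 of 100 that did decide nothing. The highest other split, which swaps before and after in a part of the pairs, gave 54 genes, and what produces them was not tested.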
